A study of Homo sapiens with 17 samples.

How the data were processed

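Bulk RNA sequencing was done on bone marrow of 2 patient-derived xenograft (PDX) models of paediatric acute myeloid leukaemia (AML), named AML903 and AML001. In a PDX model, human leukaemia cells are grown in mice. The mice had been given DMSO (the vehicle), quizartinib (an inhibitor of the receptor tyrosine kinase FLT3), palbociclib (an inhibitor of the cell cycle kinases CDK4 and CDK6) or both drugs, called the combination here. AML903 had 4 DMSO, 4 quizartinib and 1 palbociclib library, and AML001 had 2 libraries of each of the 4 treatments, 17 libraries in all. Doses, treatment times and whether numbered replicates came from separate animals are not given in the sources used here, so every p-value measures the spread between these samples. Per the labels, total RNA was isolated on spin columns that remove genomic DNA and sequenced on a NovaSeq instrument.

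The deposited table holds gene counts per library, not normalised, for 19869 RefSeq gene symbols, of which 2995 were at 0 in every library. All values are whole numbers. The submitters' processing notes name RSEM, which assigns reads to genes by an estimate, and the human genome build GRCh37 (hg19). The version of RSEM, the aligner, the strand setting, any rounding and any removal of mouse reads are not given in the sources used here, so reads of mouse cells that map to human genes stay possible. The annotation at hand is of another build, so no coordinates are given. Every column was matched to a sample by its library name in the labels, and 0 columns were left over. XIST and Y-linked genes (45 in the table) were left out of all results.

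Library totals ran from 2734619 to 39726691 counts. A gene at 0 in a group was given a floor of 3 counts over the summed total of the group, and a fold against such a group is written as "at least". Such floors cover counting error only. Levels in CPM are counts relative to the library total, without further scaling, as mean ± SD over the libraries of a group. Fold changes and log2 CPM are scaled by the trimmed mean of M-values (TMM). Folds from the floor use the summed counts, and where genes at 0 set the median of a list, the median with these genes at their floor is given as its bound.

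Genes were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filter filterByExpr on the groups of the fit, a quasi-likelihood fit and F-test, and Benjamini-Hochberg adjustment over the tested genes, with genes called at an adjusted p under 0.05. The ± after a log2 fold change is its standard error, and those without it are given by value only. AML903 was fitted on its 4 DMSO and 4 quizartinib libraries (13369 genes tested) and AML001 on all 8 libraries (12688 genes). The departure from additivity was combination minus quizartinib minus palbociclib plus DMSO. The quizartinib effect in AML903 minus that in AML001 was tested as an interaction (14339 genes), and the DMSO libraries of both models were compared directly (13653 genes), making 10 comparisons with a test. DESeq2 1.42.0 was the second tool. The single AML903 palbociclib library has no test: its log2 CPM (prior count 2) was set against the mean and range of the 4 DMSO libraries, and list medians against 10000 random lists matched on expression.

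Gene lists, 32 in number with 705 members (704 found in the table), the comparisons, the tests and the rule for named genes were fixed before the data were examined. They were drug targets and cell cycle control, E2F targets and DNA replication, mitosis, STAT5 targets, ERK output, FOXO targets, MYC and ribosome biogenesis, ATF4 and amino acid response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, p53 targets, the BCL2 family, the LSC17 stemness genes, stem and progenitor, promyelocyte granule, mature neutrophil, monocyte and macrophage, MHC class II, interferon response, NF-kB and inflammatory, homing and adhesion, drug transporters, and RNA quality and handling. The other lists hold markers of erythroid, T and NK, B and plasma, megakaryocyte and platelet, stroma, endothelium, mast with basophil and eosinophil, and dendritic cells. Lists with at least 5 tested members were tested with camera in limma 3.58.1, which asks whether a list moved relative to all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. In AML001 this left 29 lists, without the erythroid, T and NK, and B and plasma lists. No list call in any comparison held when camera estimated the correlation of each list from the data, and the adjusted p from that test is given with the calls. In AML903 every split of the DMSO and quizartinib libraries into equal groups, whatever the treatment, called at least 5 lists at the preset correlation. A list call at that correlation therefore does not by itself show a treatment effect. The test fry, which asks whether a list's genes move on balance one way, called 8 lists between the DMSO groups of the models and 0 in the other comparisons.

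Named genes were the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members with the lowest p of each called list, and the main drug target and cell cycle genes. Where under 5 genes passed, the 5 with the lowest p were taken, and members of lists are given by value only. For the AML903 palbociclib library the rule asked for called genes of the AML001 palbociclib comparison, of which there were 0, so named members of its called lists were used, chosen after the values were seen. Genes with provisional or non-coding RNA names were not named. 1 gene that met the rule for list members is not reported here.

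The library names of AML001 form 2 sets, which hold replicate 1 and replicate 2 of every treatment, so the median of each list called in an AML001 comparison, and of the lists given for additivity, is shown over all libraries and within each set (no test). The AML903 names fall into number series, 1 of which holds 2 DMSO and 3 quizartinib libraries and was fitted alone. Pairing by replicate number was checked on residual correlations after removing group means. For equal numbers these were 0.156 to 0.36 in AML903 and 0.201 to 0.456 in AML001. In AML903, 2 of the 24 pairings had all values above 0.1. Of the 8 libraries, 4 correlated best with their own number. These values met the rule fixed for pairing. The fit with the replicate number as a block is therefore given as an alternative. The main AML001 fit left differences between the sets in its spread. The DMSO groups of the models could not be paired, as their numbers have no link.

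The other alternatives were DESeq2 size factors in edgeR, no low-count filter, a minimum log2 fold change of 1, mitochondrial, ribosomal protein and haemoglobin genes left out, all 17 libraries in one fit, a prior count of 0.5, and leaving out each library in turn. Further alternatives, chosen after seeing the data, left out the 2 AML001 libraries with the most genes at 0, kept only genes with a mean of 50 CPM or more, used limma voom with a weight per library, combined these or the estimated correlation with the block, left out 1 library of each model together, and gave the simulated groups without any effect the replicate block. Where leaving out a library left 1 library in a group, that library was assumed to vary like the other groups.

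The fits were tested on simulated data with 100 genes changed 2-fold, 100 changed 4-fold and 1 list lowered by 1 log2 unit, with the depths and dispersions of the libraries. The simulated genes varied independently, and the list was tested at the preset correlation unless stated. For AML903 quizartinib, 38% of the 2-fold and 80% of the 4-fold genes were called, and so was the list. For AML001 palbociclib and the combination, 0% and 0% were called and the list was not, against 26% and 70% (palbociclib) and 16% and 55% (combination) with 0.1 of the dispersion, where the list was called. With the means of each replicate set, and the dispersions and fit of the replicate block, 0% and 0% were called in both and the list was not (adjusted p = 0.251 and 0.0726). For the interaction, 0% and 15% were called, and between the DMSO groups 0% and 29%, with the list called in each.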

Results

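The study asked how marrow of 2 PDX models of paediatric AML responds to FLT3 inhibition with quizartinib, to CDK4/6 inhibition with palbociclib, and to the combination. Library totals ran from 10927396 to 39726691 counts over the 9 AML903 libraries and from 2734619 to 14038399 over the 8 AML001 libraries. In AML001, combination replicate 2 had 2734619 counts, and 2366 of the 9061 genes with a median of at least 10 CPM in the other AML001 libraries were at 0 in it. Quizartinib replicate 2 had 5302174 counts and 585 of 9023 such genes at 0, against at most 38 in each of the other AML001 libraries and at most 19 in each AML903 library. On the first principal component of AML001, which held 70.7% of the variance of 4336 genes, combination replicate 2 lay at 139 and the others between -32.6 and 8.42. In AML903, DMSO replicate 1 stood apart: the myeloid enzyme gene LYZ took 0.241% of its counts and 2.15% to 4.63% in the other DMSO libraries.

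**Figure D1:**
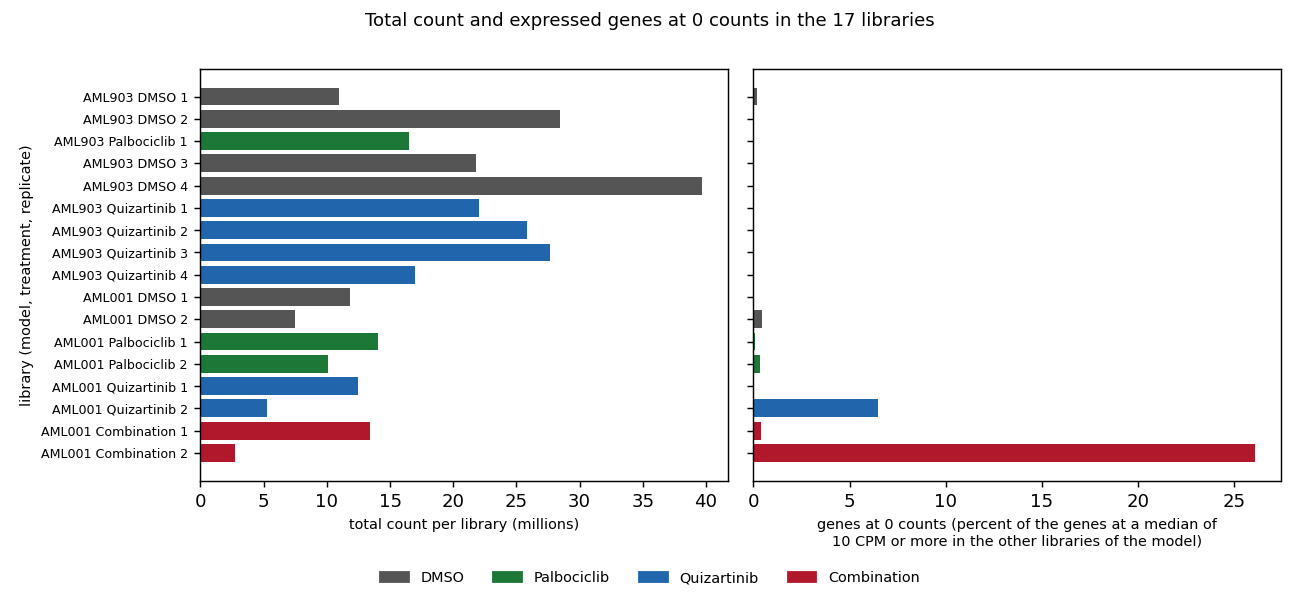
Total counts (bars, from 0) and the percentage of expressed genes at 0 for each of the 17 libraries, by model and treatment. AML001 combination replicate 2 has 26.1% and quizartinib replicate 2 has 6.48% of expressed genes at 0, while the other libraries have at most 0.424%.

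Quizartinib in AML903 (4 libraries against 4 DMSO) was accompanied by higher myeloid and lower erythroid marker lists, with adjusted p values under 0.05 at the preset correlation and an adjusted p = 0.903 for each list with an estimated correlation. The promyelocyte granule list, which holds the proteases of early granulocyte precursors, rose in 12 of 13 members with a median log2 fold change of 0.30. One member, neutrophil elastase ELANE, was at 514 CPM against 326 ± 85.5 CPM in DMSO (n = 4 each; log2 fold change 0.65 ± 0.26). The erythroid list, markers of red cell precursors, fell in 10 of 10 members (median -0.78). The mature neutrophil (14 of 18 members, median 0.17), monocyte and macrophage (21 of 25, 0.21), MHC class II (10 of 11, 0.16), interferon response (27 of 33, 0.14) and mast, basophil and eosinophil (8 of 11, 0.17) lists also rose. DMSO replicate 1 carried most of this: without it the erythroid list was at -0.07, mature neutrophil at -0.08, monocyte and macrophage at -0.14 and MHC class II at -0.25.

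Cholesterol synthesis genes fell in AML903 quizartinib (20 of 23 members, median -0.13), with MSMO1 at -0.40 ± 0.14, HMGCS1 at -0.41 ± 0.17 and SQLE, a rate-limiting enzyme of the pathway, at -0.43 ± 0.21. The p53 target list (18 of 24 members, -0.14) and the mitosis list (28 of 37, -0.07, with CENPE at -0.21 and CDK1 at -0.24) also fell. The RNA quality and handling list, which holds early response genes that react to sample handling, rose (15 of 20, 0.21). Its member FOSB, an AP-1 subunit, went from 4.14 ± 1.43 to 19.6 ± 5.73 CPM (2.27 ± 0.33, adjusted p = 0.972 over all genes). Adjusted over the list alone, 1 of the 20 members passed, FOSB (adjusted p = 0.00145), and over all genes 0 did. The adjusted p of these 11 lists was 0.00319 to 0.0469 with the preset correlation, and each had an adjusted p = 0.903 with an estimated correlation.

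With edgeR, 0 of 13369 genes were called in AML903 quizartinib, 157 had an unadjusted p under 0.05, and DESeq2 called 5. The 5 genes with the lowest p, which did not pass, were FOSB, RPL36A-HNRNPH2 (a readthrough of neighbouring genes, -2.95 ± 0.55), the DNA polymerase gene POLK (0.73 ± 0.15), the transcription factor gene CREB1 (-0.87 ± 0.18) and PYURF (-0.51 ± 0.11). Further list members by value were PRTN3 at 0.63, CEBPE at 0.30, TCN1 at 0.56, CSF3R at 0.29, and GDF15 at -1.96 and FCGR3A at 1.92, both genes near the detection limit. Some members with the lowest p went against their list: CD163 at -3.65 ± 1.58 (monocyte and macrophage, also near the detection limit), USP18 at -1.04 ± 0.36 (interferon response), FCER1A at -0.99 ± 0.39 (mast, basophil and eosinophil) and BTG2 at 0.29 (p53 targets). The drug targets and cell cycle control list was not called (29 members, median -0.04). Its members FLT3 (124 ± 106 CPM in DMSO and 137 ± 61.2 with quizartinib), CDK4 (-0.13 ± 0.13), CDK6 (-0.21 ± 0.29), CCND3 (-0.11) and CDKN1A (0.13) did not pass. E2F targets and DNA replication had a median of -0.03 (adjusted p = 0.446) and were not called.

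Among the 19 further lists not called in AML903 quizartinib, the signalling lists had medians of -0.11 (STAT5 targets), -0.16 (ERK output), -0.01 (FOXO targets) and 0.10 (NF-kB and inflammatory). MYC and ribosome biogenesis was at -0.05, ATF4 and amino acid response at -0.03, glycolysis and hypoxia at 0.04, oxidative phosphorylation at 0.002, the BCL2 family at -0.06, LSC17 at -0.02, and stem and progenitor at -0.07. Homing and adhesion was at 0.12, drug transporters at -0.05, and the cell lists at 0.41 (T and NK), 0.01 (B and plasma), -0.33 (megakaryocyte and platelet), 0.10 (stroma), 0.08 (endothelium) and 0.005 (dendritic). For 11 of the 21 lists not called, the median, the mean and the test direction differed in sign.

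Single libraries decided most of these AML903 list calls, given here as the median and adjusted p without them. Without DMSO replicate 1 the calls of promyelocyte granule (0.16, adjusted p = 0.143), erythroid (-0.07, 0.824), mature neutrophil (-0.08, 0.919), mitosis (-0.02, 0.814), monocyte and macrophage (-0.14, 0.0824) and interferon response (-0.03, 0.919) ended, and MHC class II turned to -0.25 (0.0413). RNA quality was then at 0.10, cholesterol synthesis at -0.21 and the mast cell list at 0.40. Without DMSO replicate 4 cholesterol synthesis was at 0.03 (0.965), mitosis at -0.04 (0.404), the mast cell list at 0.47 (0.162) and RNA quality at 0.27 (0.0705), and these 4 were not called. Mature neutrophil was then at 0.34, monocyte and macrophage at 0.45 and MHC class II at 0.43. Without DMSO replicate 2 the calls of p53 targets (-0.03, 0.853) and interferon response (0.12, 0.251) ended, and mitosis was at -0.13, mature neutrophil at 0.06 and the mast cell list at 0.29. Without DMSO replicate 3 the mast cell list was not called (0.26, 0.158), and cholesterol synthesis was at -0.22, mature neutrophil at 0.42, monocyte and macrophage at 0.50, MHC class II at 0.47, interferon response at 0.25 and RNA quality at 0.37. Without quizartinib replicate 1 interferon response was at 0.25 and the mast cell list at 0.38. Without quizartinib replicate 2 mitosis (-0.03, 0.422), RNA quality (0.10, 0.112), interferon response (0.18, 0.0788) and the mast cell list (0.26, 0.167) were not called, and MHC class II was at 0.24. Without quizartinib replicate 3 the monocyte and macrophage (0.03, 0.307), MHC class II (0.07, 0.0681) and interferon (0.02, 0.368) lists were not called, and mature neutrophil was at 0.03. Without quizartinib replicate 4 the monocyte and macrophage (0.14, 0.0931), MHC class II (0.14, 0.0799) and interferon (0.14, 0.169) lists were not called either. Neither were p53 targets (-0.11, 0.0931) or the mast cell list (0.10, 0.213), and erythroid was at -0.50. Within 1 series of library names (2 DMSO, 3 quizartinib) promyelocyte granule was at 0.54, mature neutrophil at 0.42, monocyte and macrophage at 0.47, MHC class II at 0.61 and interferon response at 0.25. Erythroid was at -0.91 there, cholesterol synthesis at -0.32, mitosis at -0.22 and RNA quality at 0.48, while p53 targets (-0.04, 0.943) and the mast cell list (-0.06, 0.469) were not called. With the replicate block the same 11 lists were called, erythroid at -0.47, mature neutrophil at 0.48, monocyte and macrophage at 0.52, MHC class II at 0.66 and the mast cell list at 0.46, and the other 6 moved by under 1.5 times. Without a low-count filter interferon response (0.15, 0.0573) and the mast cell list (0.17, 0.0551) were not called. With all 17 libraries in one fit neither were these (0.14, 0.137 and 0.17, 0.123), mitosis (-0.08, 0.304), cholesterol synthesis (-0.13, 0.0716), p53 targets (-0.15, 0.118) or promyelocyte granule (0.30, 0.188).

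**Figure D2:**
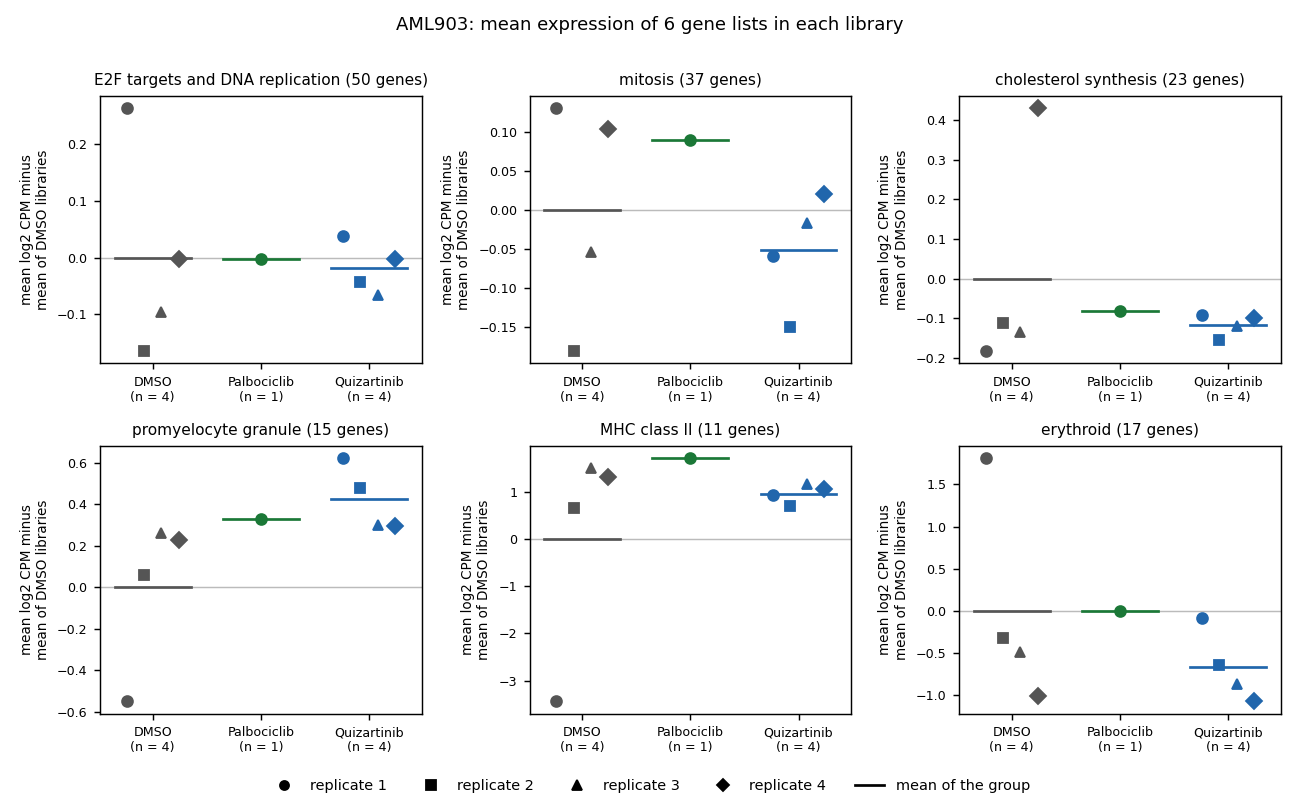
Mean log2 CPM of the members of 6 gene lists in each AML903 library, relative to the mean of the 4 DMSO libraries, by treatment (DMSO, quizartinib, palbociclib), 1 point per library. DMSO replicate 1 lies far below the other DMSO libraries for MHC class II.

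With palbociclib in AML001 (2 libraries against 2 DMSO) the proliferation lists fell. E2F targets and DNA replication, the genes switched on when cells enter S phase, fell in 50 of 50 members with a median of -1.31 (-0.91 within replicate 1 and -1.82 within replicate 2). The mitosis list fell in 37 of 37 members with a median of -2.05 (-1.33 and -3.10). MCM7, a subunit of the replicative helicase, was at 106.2 ± 14.02 CPM against 220 ± 25.5 in DMSO (n = 2 each; -1.01 ± 0.26). TOP2A, the topoisomerase of dividing cells, was at 27.6 CPM against 129 (-2.15 ± 0.75), and CDC20, an activator of the anaphase-promoting complex, at 14.8 against 77.8 (-2.30 ± 0.96). The adjusted p was 1.16e-21 for E2F targets and 9.81e-20 for mitosis with the preset correlation, and adjusted p = 0.564 for each with an estimated correlation.

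MYC and ribosome biogenesis genes also fell with palbociclib in AML001 (30 of 30 members, median -0.50; -0.58 and -0.47 within replicates 1 and 2). The adjusted p was 6.36e-10, and adjusted p = 0.564 with an estimated correlation, with MRTO4 at -0.86, NOP16 at -0.99 and the transferrin receptor gene TFRC at -0.61. Oxidative phosphorylation fell in 35 of 40 members (median -0.23; -0.15 and -0.24 within the replicates). Its adjusted p was 0.00488, and adjusted p = 0.649 with an estimated correlation, with COX8A at -0.71 and UQCRQ at -0.66. The NF-kB and inflammatory list rose in 22 of 22 members (median 0.90; 1.15 and 0.25 within the replicates; adjusted p = 1.53e-06), with the chemokine gene CXCL8 at 148 CPM against 53.4 (1.53 ± 0.45) and NFKB2 at 0.75. Monocyte and macrophage genes rose in 23 of 26 members (median 0.72; 0.81 and 0.42; adjusted p = 0.000197) and ERK output in 14 of 17 (0.76; 0.54 and 0.63, bound 0.25; adjusted p = 0.00526). Each of these 3 lists had an adjusted p = 0.564 with an estimated correlation. Members by value were CD36 at 0.78, ITGAX at 0.74, the immediate early gene IER3 at 1.40 ± 0.45 and the ERK phosphatase gene DUSP6 at 0.76. MHC class II rose in 10 of 11 members (median 0.44; 0.76 and 0.09; adjusted p = 0.0046) and mature neutrophil in 16 of 17 (0.32; 0.38 and 0.38; adjusted p = 0.0267), each with an adjusted p = 0.649 with an estimated correlation. By value, HLA-DPB1 was at 0.44, HLA-DRA at 0.48, FPR1 at 0.73 and CYBB at 0.57.

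With edgeR, 0 of 12688 genes were called in AML001 palbociclib, 40 had an unadjusted p under 0.05, 0 list members passed over all genes or adjusted over the list alone, and DESeq2 called 5, all lower, including MCM7 and SPAG5. Limma voom with a weight per library and the replicate block, chosen after seeing the data, called 85 (35 higher, 50 lower), and voom without the block 0. The genes with the lowest p, which did not pass, were the microtubule regulator STMN1 (78.2 ± 8.70 against 299 ± 110 CPM, -1.89 ± 0.46), MCM7, SPAG5 (-1.90 ± 0.50), WDR34 (-2.29 ± 0.65) and CXCL8. Other proliferation genes by value were POLE at -1.07, MCM4 at -1.17, PCNA at -1.31 ± 0.62 and KIF2C at -1.73. The drug targets and cell cycle control list was not called (median -0.06), and its members CDK4 (-0.69 ± 0.58), CDK6 (0.17), CDKN2C (-0.70), RB1 (0.29) and FLT3 (-0.07 ± 0.78) did not pass. The other lists not called had medians between -0.50 (promyelocyte granule) and 0.40 (endothelium).

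E2F and MYC calls in AML001 palbociclib held without any 1 of its libraries, and mitosis was at -3.15 without palbociclib replicate 1. Without palbociclib replicate 1 the calls of NF-kB (-0.11, adjusted p = 0.524), monocyte and macrophage (-0.16, 0.71), MHC class II (0.05, 0.982), mature neutrophil (-0.11, 0.412) and oxidative phosphorylation (-0.21, 0.0968) ended. Without palbociclib replicate 2 those of ERK output (-0.48, 0.749), mature neutrophil (0.86, 0.0669) and oxidative phosphorylation (-0.17, 0.119) did, with MHC class II at 0.82. Without DMSO replicate 1 ERK output (0.03, 0.72) and MHC class II (0.41, 0.0996) were not called and mature neutrophil was at 0.71. Without DMSO replicate 2 mature neutrophil (0.09, 0.478), monocyte and macrophage (0.32, 0.0872) and oxidative phosphorylation (-0.19, 0.0872) were not called, with ERK output at 1.36. Without the 2 AML001 libraries with the most genes at 0, which are in other groups, ERK output was not called (0.78, 0.185). Without a low-count filter mature neutrophil was not called (0.34, 0.187), nor among genes of 50 CPM or more (0.30, 0.116). With all 17 libraries in one fit neither it (0.34, 0.4) nor ERK output (0.78, 0.0536) or MHC class II (0.47, 0.396) was.

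With quizartinib in AML001 (2 libraries against 2 DMSO) the cholesterol synthesis list fell in 22 of 23 members, with a median of -0.73 that was alike within replicate 1 (-0.77) and replicate 2 (-0.68). DHCR7, the last enzyme of the pathway, was at 18.4 CPM against 62.2 in DMSO (n = 2 each; -1.79 ± 0.78), with IDI1 at -1.12, LSS at -0.87 and EBP at -0.65. The NF-kB and inflammatory list rose in 17 of 22 members (median 0.63; 0.44 and 0.72 within the replicates). The dendritic cell activation marker CD83 was at 48.7 ± 51.7 CPM against 3.94 (3.52 ± 1.48), the adhesion receptor gene ICAM1 at 1.48, NFKB2 at 1.04 and CXCL8 at 0.94. The adjusted p was 0.000309 for cholesterol synthesis and 0.000161 for NF-kB, and adjusted p = 0.561 for each with an estimated correlation.

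The proliferation lists fell with quizartinib in AML001, mostly within replicate 2, whose quizartinib library had 6.48% of expressed genes at 0. Mitosis fell in 37 of 37 members (median -1.05; -0.32 and -2.48 within replicates 1 and 2; adjusted p = 0.000139). E2F targets fell in 49 of 50 (-0.61; -0.15 and -1.11; adjusted p = 0.00289), and each had an adjusted p = 0.801 with an estimated correlation. TOP2A was at 62.9 ± 43.6 CPM against 129, CDC20 at -1.16, MCM4 at -0.66 and MCM7 at -0.34. MYC and ribosome biogenesis fell in 28 of 30 (-0.44; -0.27 and -0.74; adjusted p = 0.00326, and adjusted p = 0.703 with an estimated correlation), with NOP16 at -1.11 and the nucleolar gene NPM1 at -0.58. MHC class II rose in 11 of 11 members (median 0.62; 0.28 and 0.85; adjusted p = 0.000139) and the dendritic list in 9 of 9 (0.80; 0.41 and 0.79; adjusted p = 0.0114). The mast, basophil and eosinophil list rose in 4 of 6 (0.79; 0.41 and 2.22; adjusted p = 0.0224) and RNA quality and handling in 13 of 20 (0.19; 0.17 and 0.19; adjusted p = 0.0195). These 4 lists each had an adjusted p = 0.561 with an estimated correlation. Monocyte and macrophage rose in 20 of 26 (0.17; 0.11 and 0.27; adjusted p = 0.0278, and adjusted p = 0.801 with an estimated correlation). HLA-DPB1 was at 1113 CPM against 670 (0.67 ± 0.41), CD74 at 0.67, ATF3 at 2.5 and FCN1 at 1.47. Against their list went HSPE1 at -0.80 ± 0.44 and FOS at -0.77 ± 0.53 (RNA quality), KLF4 at -0.62 (monocyte and macrophage), CCR3 at -0.93 ± 2.82 (mast cell list, near the detection limit) and TFRC at 0.51 (MYC). With the replicate block mitosis was at -1.82 and the mast cell list at 1.67, both called, and the other called lists moved by under 1.5 times.

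With edgeR, 0 of 12688 genes were called in AML001 quizartinib, 26 had an unadjusted p under 0.05, 0 list members passed over all genes or adjusted over the list alone, and DESeq2 called 4. Among the genes with the lowest p, none of which passed, were the integrin gene ITGAX (593 ± 154 against 253 ± 64.1 CPM, 1.17 ± 0.33), ICOSLG (1.67 ± 0.50) and SH3PXD2B (2.05 ± 0.62). The drug targets and cell cycle control list was not called (median -0.16), with FLT3 at 0.49 ± 0.78, CDK4 at -0.88 and CDK6 at 0.05, and STAT5 targets, a pathway downstream of FLT3, had a median of 0.38 (adjusted p = 0.0584). Lists not called had medians between -0.67 (promyelocyte granule) and 0.48 (stroma).

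Without quizartinib replicate 2 the AML001 calls of mitosis (-0.33, adjusted p = 0.145), E2F targets (-0.19, 0.134), monocyte and macrophage (0.43, 0.134), MHC class II (0.30, 0.134), dendritic (0.05, 0.142) and RNA quality (-0.002, 0.949) ended. MYC was then at -0.19 and the mast cell list at 0.34. Without quizartinib replicate 1 those of MYC (-0.81, 0.102), cholesterol synthesis (-1.03, 0.0874) and monocyte and macrophage (-0.03, 0.196) ended, with mitosis at -2.67, E2F targets at -1.11, MHC class II at 0.94 and RNA quality at 0.39. Without DMSO replicate 1 the dendritic (0.64, 0.0622) and RNA quality (0.10, 0.245) lists were not called, with NF-kB at 1.07 (bound 0.90), the mast cell list at 5.11 (bound 2.06) and monocyte and macrophage at 0.68. Without DMSO replicate 2 monocyte and macrophage (0.02, 0.372) and the mast cell list (1.81, 0.0562) were not called, with RNA quality at 0.43. Among genes of 50 CPM or more, RNA quality (0.02, 0.838) and monocyte and macrophage (0.17, 0.277) were not called and E2F targets were at -0.35. With all 17 libraries in one fit monocyte and macrophage (0.17, 0.075) and MHC class II (0.59, 0.069) were not called. Without the 2 libraries with the most genes at 0 neither were these (0.44, 0.172 and 0.31, 0.0894), the mast cell list (0.34, 0.0564) or RNA quality (0.001, 0.921). Mitosis was then at -0.33 (0.032), E2F targets at -0.19 (0.032), MYC at -0.18 and dendritic at 0.06 (0.0499).

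With the combination in AML001 (2 libraries against 2 DMSO) the proliferation and cholesterol synthesis lists fell together and NF-kB rose, each with an adjusted p under 0.05 at the preset correlation and an adjusted p = 0.684 with an estimated correlation. Mitosis fell in 37 of 37 members (median -2.09) and E2F targets in 49 of 50 (-1.58); within replicate 1 alone these medians were -1.06 and -0.70, and within replicate 2, where 26.1% of expressed genes were at 0, they were -7.50 and -6.35 (bounds -5.09 and -3.93). Cholesterol synthesis fell in 20 of 23 members (-1.34; -0.77 and -2.78), with FDFT1, the first enzyme committed to sterols, at 74.3 ± 54.9 CPM against 179 (n = 2 each; -1.34 ± 0.59), CYP51A1 at -1.80 and EBP at -1.07 ± 0.43. The NF-kB and inflammatory list rose in 19 of 22 (0.68; 0.64 and 0.51), with NFKB2 at 178 CPM against 53.2 (1.52 ± 0.62) and IER3 at 107 against 30.4 (1.62 ± 0.45). With the replicate block mitosis was at -3.65, E2F targets at -2.43, RNA quality at 0.27 and monocyte and macrophage at -0.02, all called.

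The adjusted p in the AML001 combination was 1.61e-08 for mitosis, 1.8e-07 for E2F targets, 4.44e-06 for NF-kB and 0.000685 for cholesterol synthesis. MYC and ribosome biogenesis fell in 27 of 30 members (median -0.87; -0.48 and -1.34 within the replicates; adjusted p = 0.00535). These 5 lists each had an adjusted p = 0.684 with an estimated correlation. So did MHC class II, which rose in 11 of 11 (0.56; -0.02 and 1.0; adjusted p = 0.000291), and RNA quality, which rose in 11 of 20 (0.17; 0.46 and 0.003; adjusted p = 0.0056). Monocyte and macrophage rose in 16 of 26 (0.16; 0.40 and -0.25, bound -0.12; adjusted p = 0.0408, or 0.77 with an estimated correlation). Members by value were MCM4 at -1.32, PCNA at -1.33, RRM1 at -1.67, KIF2C at -1.62, TOP2A at -1.39, CDC20 at 21.7 CPM against 77.8 (-2.01 ± 0.95), NOLC1 at -0.93, NOP56 at -1.28, HLA-DMB at 1.11 and JUND at 1.09. Against their list went HSP90AA1 at -0.79 ± 0.35 (RNA quality) and TLR2 at -0.66 (monocyte and macrophage).

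With edgeR, 0 of 12688 genes were called in the AML001 combination, 147 had an unadjusted p under 0.05, 0 list members passed over all genes or adjusted over the list alone, and DESeq2 called 21 (5 higher, 16 lower). With all 17 libraries in one fit 5 genes were called, all lower. The 5 genes with the lowest p did not pass, although all but ITGAX were among those called in that fit: ITGAX was at 715 ± 292 CPM against 253 (1.30 ± 0.33). KLHL8, CARNMT1, NAIF1 and PCGF6 were at 0 in both combination libraries, at least 177-, 85.9-, 70.1- and 67.3-fold lower than in DMSO. These bounds were 147-, 71.3-, 58.2- and 55.9-fold from combination replicate 1 alone, and 30.1-, 14.6-, 11.9- and 11.4-fold from replicate 2. In that library 56% of genes with a median of 10 to 20 CPM were at 0, and 33.9% of those from 20 to 50 CPM. A 0 there therefore bounds no level. The median log2 fold change of all genes was -0.29 with TMM. Drug targets and cell cycle control was not called (median -0.49), with FLT3 at -0.45, CDK4 at -0.32 and CDK6 at -0.62. Other lists not called had medians between -0.98 (promyelocyte granule) and 0.80 (mast, basophil and eosinophil). The median, mean and test direction differed in sign for 9 of the lists not called with quizartinib, 4 with palbociclib and 9 with the combination, and for 0 of those called.

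Without combination replicate 2 the AML001 combination had mitosis at -1.19, E2F targets at -0.72, cholesterol synthesis at -0.74, MYC at -0.43 and monocyte and macrophage at 0.55, all called. MHC class II (0.07, adjusted p = 0.835) and RNA quality (0.23, 0.405) were not called. Without combination replicate 1, when 2573 genes were called, mitosis was at -11.4 (bound -5.05) and E2F targets at -10.4 (bound -4.09), NF-kB was at 0.42 and MHC class II at 1.03, and MYC (-1.25, 0.411), cholesterol synthesis (-2.93, bound -2.65, 0.173) and monocyte and macrophage (-0.91, 0.529) were not called. Without DMSO replicate 1 RNA quality was not called (-0.15, 0.0768) and monocyte and macrophage was at 0.44. Without DMSO replicate 2 monocyte and macrophage was not called (-0.11, 0.229) and RNA quality was at 0.40. Among genes of 50 CPM or more, cholesterol synthesis was at -0.61, and monocyte and macrophage (0.21, 0.561) and RNA quality (0.09, 0.455) were not called. Monocyte and macrophage was also not called without a low-count filter (0.17, 0.0577) or with all 17 libraries in one fit (0.13, 0.0602). Genes moved with the same libraries: without combination replicate 1 and without its replicate 2, in that order, FDFT1 was at -2.65 and -0.65, CYP51A1 at -3.50 and -1.04 and EBP at -1.51 and -0.71. MCM4 was at -2.37 and -0.70, PCNA at -2.38 and -0.70, NOP56 at -2.47 and -0.62, JUND at 1.59 and 0.36 and HLA-DMB at 1.79 and -0.16.

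**Figure D3:**
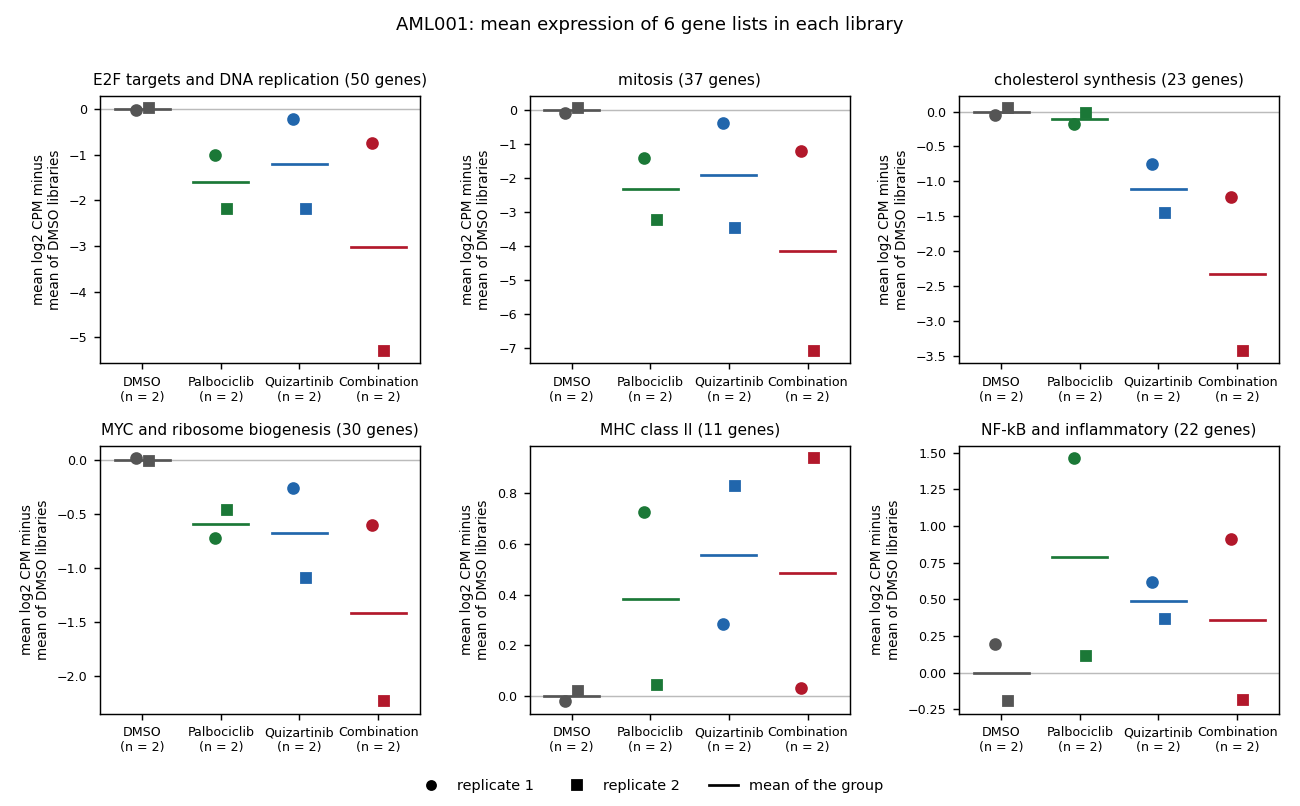
Mean log2 CPM of the members of 6 gene lists in each AML001 library relative to the mean of the DMSO libraries, by treatment, with replicate 1 as circles and replicate 2 as squares. Mitosis and E2F lists lie below DMSO in both palbociclib libraries, and combination replicate 2 lies far below the rest.

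The AML001 treatments were also set against each other. Quizartinib libraries had higher proliferation lists than palbociclib libraries: E2F targets in 47 of 50 members (median 0.67; 0.68 and 0.30 within replicates 1 and 2; adjusted p = 0.000182) and mitosis in 34 of 37 (1.08; 1.04 and -0.25; 0.015). Cholesterol synthesis (20 of 23 lower, -0.56; -0.58 and -0.91; 0.0127) and mature neutrophil (15 of 17 lower, -0.75; -0.56 and -1.51; 0.0212) were lower with quizartinib than with palbociclib, and all 4 lists had an adjusted p = 0.941 with an estimated correlation. With the replicate block mitosis was at 0.50 (0.0164). By value, MCM7 was at 0.66 ± 0.26, POLE at 0.77, TOP2A at 1.09, KIF2C at 1.14, TFRC at 1.12 ± 0.35, WDR34 at 2.15 ± 0.65, DHCR7 at -1.30, FPR1 at -1.11 and CYBB at -1.04, and none passed. With edgeR, 0 genes were called, 39 had an unadjusted p under 0.05, and DESeq2 called 5. Without palbociclib replicate 2 none of the 4 was called (E2F 0.28, 0.259; mitosis 0.38, 0.858; cholesterol -0.60, 0.113; neutrophil -1.30, 0.0675). Without quizartinib replicate 1 none was either (E2F 0.002, 0.588; mitosis -0.77, 0.978; cholesterol -1.12, 0.247; neutrophil -2.32, 0.142). Mature neutrophil was also not called without palbociclib replicate 1 (0.09, 0.221; E2F 1.22, mitosis 2.07) or quizartinib replicate 2 (-0.19, 0.464; E2F 1.07, mitosis 1.70), and among genes of 50 CPM or more neither it (-0.66, 0.0741) nor cholesterol synthesis (-0.39, 0.113) was. Mature neutrophil was not called without a low-count filter (-0.74, 0.112) or with all 17 libraries in one fit (-0.74, 0.279).

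Against quizartinib alone, the AML001 combination had lower E2F targets (45 of 50 members, median -0.92; -0.48 and -2.65, bound -2.23, within replicates 1 and 2) and mitosis (34 of 37, -1.03; -0.75 and -4.63, bound -2.27). Each had an adjusted p = 0.0153, and an adjusted p = 0.896 with an estimated correlation. KIF2C was at -1.03 ± 0.71, PCNA at -0.69, MCM4 at -0.66 and UBP1 at -1.46 ± 0.34, and none passed. Against palbociclib alone, the combination had lower cholesterol synthesis (19 of 23 members, -1.0; -0.61 and -2.72; adjusted p = 0.017, and adjusted p = 0.984 with an estimated correlation). FDFT1 was at -1.25 ± 0.59, SQLE at -3.59 ± 1.74 and UBP1 at -1.26 ± 0.34, and none passed. With edgeR, 0 genes were called in each, 110 and 104 had an unadjusted p under 0.05, and DESeq2 called 29 and 25. Against quizartinib, both calls ended without combination replicate 2 (E2F -0.17, 0.867; mitosis -0.16, 0.868) or quizartinib replicate 1 (-0.16, 0.959; 0.60, 0.959), with medians of -9.56 and -10.6 (bounds -3.57 and -4.57) without combination replicate 1 and of -1.41 and -1.71 without quizartinib replicate 2. Without the 2 libraries with the most genes at 0 E2F targets were at -0.49. E2F targets were not called among genes of 50 CPM or more (-0.37, 0.36). Against palbociclib, the cholesterol call ended without palbociclib replicate 2 (-1.07, 0.076), without combination replicate 1 (-2.80, 0.323) and among genes of 50 CPM or more (-0.54, 0.371), and the median was -0.64 without combination replicate 2. Without combination replicate 1, SQLE was at 0 and FDFT1 at -2.56 against palbociclib. The floor put SQLE at least 22.7-fold lower, but from combination replicate 2 alone, where 26.1% of expressed genes were at 0. Without combination replicate 2 SQLE was at -2.65 and FDFT1 at -0.57. Against quizartinib MCM4 was at -1.71 without combination replicate 1 and at -0.06 without its replicate 2. With all 17 libraries in one fit 7 genes were called against quizartinib, UBP1 among them, and 5 against palbociclib. Without combination replicate 1, 2482 genes were called against quizartinib and 2450 against palbociclib.

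The departure of the AML001 combination from the sum of the single drugs was 0.62 for E2F targets (0.51 and -0.29, bound 0.54, within replicates 1 and 2; adjusted p = 0.501) and 1.05 for mitosis (0.46 and -1.69, bound 0.70; 0.534), and 0 of 29 lists were called. Other medians were -0.14 for cholesterol synthesis (0.23 and -0.69) and 0.18 for MYC (0.33 and -0.17, bound 0.04). They were -0.71 for NF-kB (-1.02 and -0.45, bound -0.245) and -0.48 for MHC class II (-1.06 and 0.10). With edgeR, 0 genes were called, 55 had an unadjusted p under 0.05, DESeq2 called 12, and 4 were called with all 17 libraries in one fit. The number of lists called was 4 without combination replicate 2, 2 without palbociclib replicate 1 and 1 without quizartinib replicate 2, and 1967 genes were called without combination replicate 1. In the 3 comparisons with DMSO, log2 fold changes across the 12688 genes correlated at 0.341 (quizartinib and palbociclib), 0.336 (quizartinib and combination) and 0.31 (palbociclib and combination). Simulated groups without any effect, set against the same shared DMSO libraries, gave 0.501, 0.498 and 0.5, and 0.497, 0.495 and 0.496 with the means and spread of a fit with the replicate block. Correlations of this size therefore do not by themselves show a shared effect. As 0 genes were called in each, 0 were shared.

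In AML903 a single palbociclib library was compared with the 4 DMSO libraries, without a test. A library without any effect would also often lie outside the range of 4 others by chance. Values outside that range therefore do not by themselves show a response to palbociclib. E2F targets were split evenly (25 members higher, 25 lower, median -0.01) and mitosis had a median of 0.05, both inside the central 95% of 10000 random lists. Lists outside the range of the 4 DMSO libraries were MYC and ribosome biogenesis (-0.19), LSC17 (-0.79), stem and progenitor (-0.65), endothelium (-0.75), the mast, basophil and eosinophil list (-0.77) and T and NK (1.25). Of the 32 lists, 14 lay outside the central 95% of the random lists, among them those 6 but endothelium. The other 9 lay inside the DMSO range: MHC class II (1.65), monocyte and macrophage (1.31), mature neutrophil (0.96), interferon response (0.47), promyelocyte granule (0.45), STAT5 targets (-0.53), NF-kB (-0.31), homing and adhesion (-0.17) and stroma (-0.545). CDK6 was at -0.87, the cyclin gene CCND2 at -1.11 and CDKN1B at -0.33, each below the 4 DMSO libraries, and CCND3 at 0.29 was above them. FLT3 (0.30), CDK4 (-0.04), RB1 (-0.04), CCND1 (-0.24), CDKN1A (0.49) and CDKN2C (0.74) lay within their range. Genes named in the AML001 palbociclib comparison were at -0.20 (MCM7), -0.23 (POLE), -0.04 (MCM4), 0.09 (PCNA), -0.31 (TOP2A), 0.22 (KIF2C), 0.17 (CDC20), 0.06 (STMN1), -0.02 (SPAG5), 0.90 (CXCL8), -0.04 (IER3), 1.23 (ITGAX) and 0.99 (CD36). Of these, TOP2A was below the 4 DMSO libraries and CDC20, CXCL8, ITGAX and CD36 were above them. Palbociclib log2 fold changes in the models correlated at 0.0528 across 12417 genes, which are not independent replicates, and 18 of the 40 genes with an unadjusted p under 0.05 in AML001 had the same sign in AML903.

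The quizartinib effect in AML903 minus that in AML001 was tested as an interaction. It was positive for mitosis (37 of 37 members, median 0.91; adjusted p = 5.86e-11), E2F targets (47 of 50, 0.60; adjusted p = 2.33e-07) and MYC and ribosome biogenesis (26 of 30, 0.40; adjusted p = 0.00396), each with an adjusted p = 0.795 with an estimated correlation. It was also positive for cholesterol synthesis (20 of 23, 0.55; adjusted p = 0.000247, and adjusted p = 0.786 with an estimated correlation). By value, the helicase subunit gene MCM2 was at 2.70 ± 0.40 (adjusted p = 0.10), AURKB at 1.45, FOXM1 at 0.91, FEN1 at 0.83, NOP16 at 1.11, DHCR7 at 1.69 ± 0.53 and EBP at 0.60. Promyelocyte granule was positive in 14 of 14 members (0.86; adjusted p = 0.00939, and adjusted p = 0.795 with an estimated correlation), with CEBPA at 0.55. The dendritic list was negative in 10 of 10 (-1.04; adjusted p = 0.0012) and NF-kB in 14 of 22 (-0.37; adjusted p = 0.00321), each with an adjusted p = 0.186 with an estimated correlation. The receptor gene IL3RA was at -2.30 ± 0.61 and CD83 at -3.64 ± 0.90. The mast, basophil and eosinophil list was negative in 7 of 12 (-0.08, bound -0.0362, adjusted p = 0.0316, and adjusted p = 0.316 with an estimated correlation).

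With edgeR 1 of 14339 genes was called in the interaction, 591 had an unadjusted p under 0.05, and DESeq2 called 36. The called gene was the helicase gene DDX31, at 0 in both AML001 quizartinib libraries and measured in all AML903 libraries. It was at least 77.2-fold lower than in AML001 DMSO (fitted difference of the interaction 10.9, at least 71.9-fold, adjusted p = 0.0145). The interaction bound was 50.4-fold from AML001 quizartinib replicate 1 alone and 21.5-fold from replicate 2. In that library 18.7% of genes with a median of 10 to 20 CPM were at 0. Adjusted over the list alone, 1 member each passed in the E2F, NF-kB, dendritic and mast cell lists, against 0 over all genes. FLT3 was at -0.36 ± 1.19. The median difference of all genes was 0.12. Across 12182 genes the quizartinib fold changes of the models correlated at 0.0242, with 51.7% of the same sign.

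Without AML001 quizartinib replicate 2 the interaction calls of E2F targets (0.13), MYC (0.10), promyelocyte granule (0.10) and NF-kB (-0.24) ended. So did those of dendritic (-0.67) and the mast cell list (-0.17, bound -0.399), and mitosis held at 0.28. Without AML001 quizartinib replicate 1 MYC (0.91), cholesterol synthesis (1.07) and the mast cell list (0.12, or -1.66 with floors) were not called. Mitosis was then at 2.82, E2F targets at 1.16, promyelocyte granule at 3.95 (3.26 with floors) and NF-kB at -0.04. The number of genes called was then 2981. Promyelocyte granule was not called without AML001 DMSO replicate 1 (0.31; NF-kB -0.73, bound -0.39). It was at 1.35 without AML001 DMSO replicate 2, where the mast cell list was not called (-0.14, bound 0.26). NF-kB was at -0.69 without AML903 DMSO replicate 4. The mast cell list was not called without AML903 DMSO replicate 1 (-0.007, bound -0.07, 0.136) or quizartinib replicate 3 (0.02, 0.0932). Nor was it with DESeq2 size factors (-0.12, 0.064) or all 17 libraries in one fit (-0.08, 0.0865). Within 1 AML903 name series MYC (0.32, 0.145) and NF-kB (-0.25, 0.074) were not called and 0 genes were, while dendritic was at -1.64 and the mast cell list at -0.53 (0.0249). With the replicate block, 0 genes were called, mitosis was at 1.53, promyelocyte granule at 1.59 and NF-kB at -0.13, and the mast cell list was not called (-0.36, 0.0776). The number of genes called was 0 without AML903 DMSO replicate 2 or 4, without AML903 quizartinib replicate 1 or 2 and with all 17 libraries in one fit, so DDX31 was not called there. It was 2 without AML903 DMSO replicate 1 or AML001 DMSO replicate 2, 4 without AML001 quizartinib replicate 2 and 15 without AML001 DMSO replicate 1.

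Under DMSO 13 lists were called between the models at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.283. Model, donor and any batch of the experiments cannot be told apart in this comparison. The labels do not say whether the models were processed together. The stem and progenitor list was lower in AML001 than in AML903 in 20 of 22 members (median -3.36, or -2.59 with genes at 0 set to their bound), and LSC17, a stemness score, in 13 of 16 (-3.17). The erythroid (11 of 11 lower; -9.14, bound -5.00), mast, basophil and eosinophil (10 of 12; -8.45, bound -5.93), stroma (11 of 12; -3.50, bound -2.88) and endothelium (5 of 6; -4.95, bound -2.47) lists were lower too. Monocyte and macrophage (22 of 26 higher, 0.98), MHC class II (11 of 11, 1.88) and NF-kB and inflammatory (15 of 21, 0.79) were higher in AML001. The monocyte receptor gene CD14 was at 851 ± 487 CPM in AML001 (n = 2) and 36.7 ± 24.4 in AML903 (n = 4; 4.598 ± 0.81, adjusted p = 0.0209).

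E2F targets (41 of 50 members lower, -0.73) and mitosis (33 of 37, -0.35) were lower in AML001, and ATF4 and amino acid response (20 of 24, 0.79) and glycolysis and hypoxia (23 of 28, 0.39) were higher. The adjusted p was 4.93e-05 for the stem and progenitor, erythroid and mast cell lists, 0.00154 for LSC17 and NF-kB, and 0.0139 for endothelium, each with an adjusted p = 0.283 with an estimated correlation. It was 0.00277 for stroma (adjusted p = 0.434 with an estimated correlation) and 0.0187 for mitosis (adjusted p = 0.805 with an estimated correlation). For E2F targets (0.000301), monocyte and macrophage (0.000445), ATF4 (0.0034), MHC class II (0.00352) and glycolysis (0.00424), it was adjusted p = 0.688 with an estimated correlation.

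Of 13653 genes tested between the DMSO groups, 1474 were called with edgeR, 651 higher and 823 lower in AML001, and 1304 of them by at least 2-fold. DESeq2 called 3148. Among the largest, the homeobox gene PITX1 was at 184 ± 27.0 CPM in AML001 and 0 in the 4 AML903 libraries (at least 6060-fold higher, adjusted p = 0.00457), as were the interleukin receptor gene IL7R (at least 1510-fold) and SLAMF7 (844-fold). IL7R was at 2.789 and 111.8 CPM in AML001 DMSO replicates 1 and 2: its bound was 3760-fold without replicate 1 and 93.8-fold without replicate 2, and that of SLAMF7 was 10.9 and 7.55 log2 units. Without AML903 DMSO replicate 4 the bounds were 3670-fold (PITX1), 918-fold (IL7R) and 512-fold (SLAMF7). At 0 in AML001 DMSO were SOX11 (at least 956-fold lower), SELENOP (858-fold), CRISP3 (812-fold), the homeobox gene HOXB9 (697-fold, adjusted p = 0.0053) and the mast cell protease gene CPA3 (585-fold). So were the erythroid and stem cell factor TAL1 (400-fold), the tryptase gene TPSB2 (273-fold), RHAG (259-fold), LUM (224-fold), HBA1 (59.1-fold) and the endothelial receptor gene TEK (39.2-fold). The bounds of genes at 0 in AML001 follow its depth, and were lower without either of its DMSO libraries, such as 370-fold for SOX11 and 155-fold for TAL1 without replicate 1. The bound of RHAG was 165-fold without AML903 DMSO replicate 1, and that of TEK 21.1-fold without AML903 DMSO replicate 2. HDC, which makes histamine, was at 0.127 CPM in AML001 and 281 in AML903.

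Called members of lists between the DMSO groups included LAPTM4B (-5.41 ± 0.86), SMIM24 (-6.55), MLLT3 (-7.06 ± 1.02), HOXA10 (-1.21), SPARC (-3.70) and EGFL7 (-3.20). Higher in AML001 were the chemokine genes CXCL8 (4.58 ± 0.39) and CCL2 (5.01 ± 0.44), FCGR3A (6.09), the glycolytic regulator PFKFB3 (2.96 ± 0.27), SLC2A3 (2.25), MTHFD2 (1.84 ± 0.25) and DDIT3 (1.70). Of the proliferation genes, MCM2 (-1.33 ± 0.24), TK1 (-1.21), PTTG1 (-1.10) and CCNB2 (-0.95) were called. Of the drug targets list (3 members called, list median -0.18, not called), CDK6 was lower in AML001 (80.2 against 413 CPM, -2.27 ± 0.45, adjusted p = 0.0275) and CDKN1A higher (220 against 68.8 CPM, 1.76 ± 0.30, adjusted p = 0.0197). FLT3 (-2.35 ± 1.07, 23.8 against 124 CPM, adjusted p = 0.186), CCND2 (-2.38, 0.0899) and CDK4 (-0.74, 0.0746) did not pass. Members called over all genes, with the count adjusted over the list alone in brackets, were 8 (21) of E2F targets, 2 (2) of mitosis, 5 (6) of ATF4, 5 (6) of glycolysis, 7 (10) of LSC17 and 9 (14) of stem and progenitor. They were 4 (6) of monocyte and macrophage, 0 (0) of MHC class II, 4 (8) of NF-kB, 4 (9) of erythroid, 4 (5) of stroma, 2 (4) of endothelium and 7 (9) of the mast cell list. Lists not called had medians between -3.73 (megakaryocyte and platelet, bound -2.73) and 0.65 (ERK output).

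The number of genes called between the DMSO groups was 212 without AML903 DMSO replicate 2, 628 without replicate 3, 609 without replicate 4, 626 without AML001 DMSO replicate 1 and 267 without its replicate 2. The mitosis call ended without AML903 DMSO replicate 1 (-0.30, adjusted p = 0.101), AML903 DMSO replicate 4 (-0.30, 0.0677) or AML001 DMSO replicate 1 (-0.36, 0.172). Without AML001 DMSO replicate 1 ATF4 (0.24, 0.309) and glycolysis (0.07, 0.143) were not called and monocyte and macrophage was at 0.53, and without its replicate 2 ATF4 was at 1.25, glycolysis at 0.74 and stroma at -7.16 (bound -2.95). Endothelium was at -3.24 (bound -2.79) without AML903 DMSO replicate 2 and -3.30 (bound -2.69) without replicate 3. Of 36 called genes taken by the rule for named genes, 35, 11, 25 and 24 passed without AML903 DMSO replicates 1 to 4 in turn, and 18 and 13 without AML001 DMSO replicates 1 and 2. All 36 kept their direction, and without AML001 DMSO replicate 1 MLLT3 was at 0 in AML001 (at least 116-fold lower) and EGFL7 was at -5.23.

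**Figure D4:**
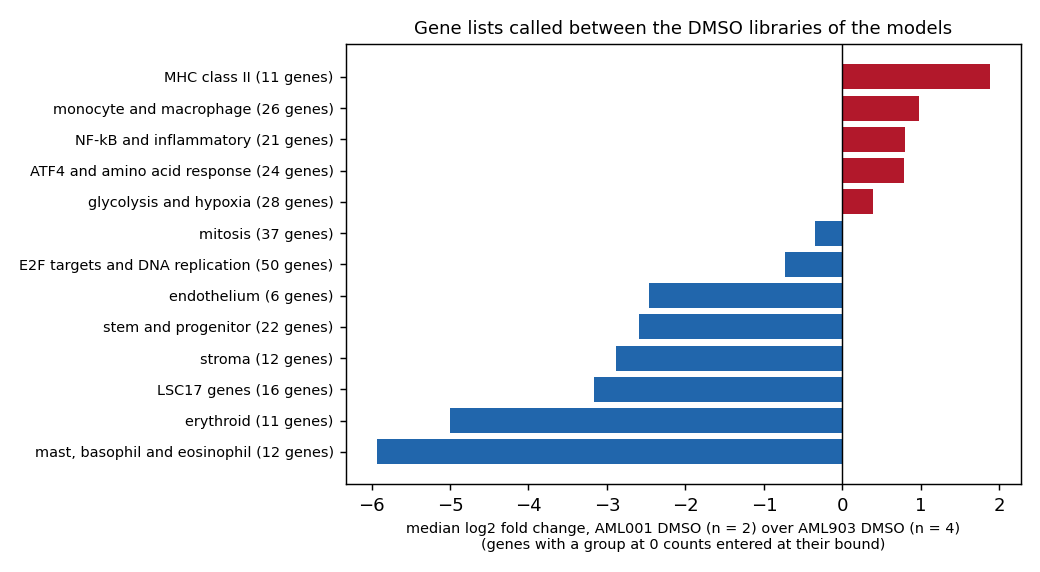
Median log2 fold change of AML001 DMSO over AML903 DMSO (bars, from 0) for the 13 gene lists called, with genes at 0 in a group set to their bound. The mast, basophil and eosinophil list has the lowest median (-5.93) and MHC class II the highest (1.88).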

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

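Of the tests in this part, those on thinned libraries, low counts, haemoglobin, the sparse libraries, the estimated correlation and the splits of genes were chosen only after the result was seen; those on overlapping genes, the other model and the splits of lists were set before.

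AML001 combination replicate 2 and quizartinib replicate 2, the sparse libraries, had 2399 and 612 of 9090 expressed genes at 0. Lower depth is argued against, since the other AML001 libraries thinned to the total of combination replicate 2 had at most 41 such genes at 0 (39 for quizartinib replicate 2). Reads shared between overlapping genes are argued against too, since 60% of the genes at 0 in combination replicate 2 overlap another gene, against 58.2% of the other expressed genes. Few starting RNA molecules stay open as a candidate explanation, since 197 genes had 1 to 9 counts in combination replicate 2 against at least 1892 in the thinned libraries, and the share at 0 fell from 56% of genes with a median of 10 to 20 CPM to 1.42% of those from 200 CPM. No biological explanation was tested, and the libraries of both treatments that include quizartinib are affected in replicate 2 alone.

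AML903 DMSO replicate 1 had 19 expressed genes at 0 against 1 to 4 in the other DMSO libraries, a mean log2 CPM of 2.673 for MHC class II against 6.768 to 7.607, and a log2 CPM of 7.56 for ELANE against 8.49 to 8.592. Maturing human erythroid cells as the main part of the sample are argued against by haemoglobin genes at 0.00443% of its counts, although the erythroid genes ALAS2 (287.5 against 7.854 to 21.85 CPM in the other DMSO libraries) and KLF1 (112.5 against 14.5 to 67.53) were higher in it, so earlier erythroid cells stay open. A library of AML001 under this label is argued against, since only 12.3% of the 1859 genes that separate the other DMSO libraries of the models lay nearer AML001 in it. Among 208 groups of values tested for a sample far from the others, 11 had one, of which 3 were this library. Chance gives about 5%, which is about this share, so these flags do not by themselves set a library apart. A different mix of leukaemia cells in this sample may remain, and no biological explanation was tested.

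The lower E2F and mitosis lists in AML001 were weighed against the 2 sparse libraries. Without them the mitosis median with the combination was -1.18 (adjusted p = 1.9e-07), which argues against them as the whole cause there; neither is compared in palbociclib against DMSO, so the median of -2.01 without them there decides nothing. With quizartinib it went from -1.05 to -0.326 (0.032), so they may account for most of that median. Chance movement of genes that vary together could not be told apart from a palbociclib effect: the mitosis list had an adjusted p of 0.564 with an estimated correlation, or 0.537 with the replicate block as well. In simulated data with the spread of either fit a list lowered by 1 log2 unit was not called at the preset correlation. The real list, at a median of -2.05, was called at that correlation, and the simulated genes varied independently. The simulation therefore decides nothing here. A lower expression of cell cycle genes under CDK4/6 inhibition, the explanation that the design gives, stays open as a hypothesis.

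In AML903 quizartinib the real split of the 8 libraries called 0 genes, so that all 35 splits gave as many decides nothing. The highest other called 1631 and parted replicates 1 and 2 from 3 and 4, with 0 of the number pairs parted, which points to a structure of the samples. The replicate block gave 0 called genes. For lists, chance is not excluded: 9 of the 35 splits gave at least as many as the real 11, with 14 the highest other. Among the 8 splits that part all 4 pairs, 3 did, with 12 the highest other, and the replicate block again gave 11. The fewest lists that any of the 35 splits called was 5, so calls at the preset correlation arise there under any split.

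Further single libraries lay far from the rest of their group. AML903 DMSO replicate 4 had a mean log2 CPM of 6.093 for cholesterol synthesis against 5.48 to 5.551. AML903 DMSO replicate 3 had a log2 CPM of 6.288 for FOXM1 against 6.657 to 6.702, and of 3.859 for IL3RA against 4.697 to 4.841. AML903 DMSO replicate 2 had 4.968 for NOP16 against 5.419 to 5.454. AML903 quizartinib replicate 3 had 1 expressed gene at 0 against 3 in each of the others, and a log2 CPM of -0.9403 for CD163 against -3.542, the value of a gene at 0, in each of them. AML903 quizartinib replicate 4 had a mean log2 CPM of 4.441 for p53 targets against 4.593 to 4.621, and of -1.635 for FCGR3A against 0.4242 to 0.5139.

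The quizartinib effect differed between the models by the interaction test (AML903 minus AML001) by 0.604 for E2F targets, 0.908 for mitosis, 0.398 for MYC and ribosome biogenesis, 0.554 for cholesterol synthesis and 0.86 for promyelocyte granule. It differed by -0.367 for NF-kB, -0.0762 (bound -0.0362) for the mast, basophil and eosinophil list and -1.04 for dendritic. The adjusted p with an estimated correlation was 0.186 or more for all 8. Without AML001 quizartinib replicate 2 E2F targets were at 0.128, mitosis at 0.278, MYC at 0.104 and promyelocyte granule at 0.102. NF-kB was then at -0.235, the mast cell list at -0.17 (bound -0.399) and dendritic at -0.669. Of these lists mitosis alone was called. DDX31 differed by a fitted 10.9 (at least 71.9-fold); besides both AML001 quizartinib libraries it was at 0 in AML001 combination replicate 2, and it was at 9.64 CPM in combination replicate 1.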

How the results depend on the processing

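The alternatives with libraries left out in pairs, a mean of 50 CPM or more, voom with weights, and the block combined with another choice were chosen after seeing the data. Of 1531 values of named genes under settings other than leaving out 1 library, 1486 kept direction and side of the threshold, 3 no longer passed, 29 newly passed and 13 reversed. Of 657 values of called lists, 374 kept, 280 were no longer called and 3 reversed. When 1 library was left out, 839 of 984 gene values and 305 of 398 list values kept. AML903 palbociclib medians each moved by less than the DMSO SD, too wide a limit to test lists such as MHC class II (3.06). AML001 combination replicate 2 had 2734619 counts and 7416 genes detected, against at least 12450 detected in the other AML001 libraries but quizartinib replicate 2, thinned to that total. The cause of the changes was not tested, except that leaving out libraries or genes leaves fewer to test.

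With an estimated correlation 0 lists were called in any comparison, with or without the replicate block, and fry called 0 except 8 between the DMSO groups; with the block fry called 1 in the combination against DMSO, 1 against palbociclib and 0 elsewhere. DESeq2 called 5 genes in AML903 quizartinib, and in AML001 4 (quizartinib), 5 (palbociclib), 21 (combination), 29 (combination against quizartinib), 25 (against palbociclib), 5 (quizartinib against palbociclib) and 12 (additivity), 36 in the interaction and 3148 between the DMSO groups. With all 17 libraries in one fit, 6 lists were called in AML903 quizartinib, and 5, 7, 5 and 4 genes in the combination against DMSO, quizartinib and palbociclib and in additivity, and 0 in the interaction. With edgeR and the replicate block 0 genes were called in all AML001 comparisons and the interaction. List counts with the block were 11 (AML903 quizartinib), 11, 10 and 9 (AML001 quizartinib, palbociclib, combination), 2, 2, 4 and 0 (the other AML001 comparisons, in the order given above) and 10 (interaction). With a mean of 50 CPM or more, 6 lists were called in AML001 quizartinib, 0 in the combination against quizartinib, 0 against palbociclib and 1 in quizartinib against palbociclib. With the block as well 0, 2 and 1 in the combination against quizartinib, quizartinib against palbociclib and additivity. Voom with weights and the block called 85 genes in AML001 palbociclib (35 higher, 50 lower). Without quizartinib replicate 2 and combination replicate 2 of AML001, 3 lists were called in the combination against palbociclib and 5 in additivity. In the interaction, 0 genes were called within 1 name series and 3 without AML903 DMSO replicate 1 and AML001 quizartinib replicate 2.

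Reversed values (log2) were, in AML903 quizartinib, FLT3 at -0.14 and the p53 list at -0.042 within 1 name series (the test turned while the median kept its sign), and FLT3 at -0.25 and CDK6 at 0.13 with voom. In AML001 quizartinib CDK6 was at -0.10 with the block and -0.05 with the block and 50 CPM, FCN1 at -0.44 and CCR3 at 0.06 without both sparse libraries, and the RNA quality list at 0.0204 with 50 CPM and 0.0135 with the block as well (the test turned). FLT3 was at 0.04 in AML001 palbociclib with the block, 0.11 with voom, and 0.15 in the interaction with the block. Without both sparse libraries the combination had HLA-DMB at -0.16, TLR2 at 0.05 and CDK6 at 0.17.

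When 1 library was left out, lists called ranged from 6 to 13 (AML903 quizartinib), 5 to 11 (AML001 quizartinib), 7 to 11 (palbociclib), 5 to 8 (combination), 0 to 4 (combination against quizartinib), 0 to 5 (against palbociclib), 0 to 8 (quizartinib against palbociclib), 0 to 4 (additivity), 2 to 10 (interaction) and 11 to 15 (DMSO groups). Genes called ranged from 0 to 2573 (combination), 0 to 2482 (against quizartinib), 0 to 2450 (against palbociclib) and 0 to 1967 (additivity), all highest without combination replicate 1, from 0 to 2981 in the interaction, highest without AML001 quizartinib replicate 1, and from 212 to 1859 between the DMSO groups, highest without AML903 DMSO replicate 1. In AML903 quizartinib and the other AML001 comparisons 0 were called.

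Values that reversed when 1 library was left out ranged as follows. In AML903 quizartinib FLT3 ranged from -0.27 to 0.58, CDK6 from -0.38 to 0.14, CDKN1A from -0.03 to 0.39, cholesterol synthesis from -0.224 to 0.028, monocyte and macrophage from -0.135 to 0.504, MHC class II from -0.245 to 0.472 and interferon response from -0.025 to 0.252. In AML001 quizartinib FCN1 ranged from -0.45 to 2.27, CCR3 from -5.94 (bound -0.25) to 1.24, FOS from -1.37 to 0.30 and CDK6 from -0.51 to 0.47. In palbociclib DUSP6 ranged from -0.06 to 1.33, FPR1 from -0.11 to 1.34, NFKB2 from -0.10 to 1.32 and FLT3 from -0.44 to 0.43. In the combination HLA-DMB ranged from -0.16 to 1.79, TLR2 from -2.00 to 0.04, FLT3 from -0.84 to 0.06 and CDK6 from -2.34 to 0.17. The mitosis list ranged from -10.6 (bound -4.57) to 0.601 in the combination against quizartinib and from -0.773 to 2.07 in quizartinib against palbociclib, and FLT3 from -0.82 to 0.11 in the interaction.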

Other observations

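AML001 replicate sets differed in some genes whatever the treatment. Genes in this part were chosen after their values were seen, without a further test. The proteoglycan gene VCAN was at 1388 to 2247 CPM in the 4 replicate 1 libraries and at 23.0 to 55.3 CPM in the 4 replicate 2 libraries. The scavenger receptor gene CD163 was at 173 to 480 against 0 to 4.05 CPM, and CD300E at 178 to 406 against 0 to 10.8 CPM. Other genes were higher in replicate 2: the complement gene C1QA at 79.5 to 256 against 8.03 to 28.8 CPM, and the IgE receptor gene FCER1A at 158 to 653 against 39.6 to 74.4 CPM. IL7R was at 112 to 476 against 2.79 to 26.7 CPM, and the MAP kinase phosphatase gene DUSP4 at 137 to 696 against 2.97 to 7.48 CPM.

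The receptor gene MERTK was higher with each treatment than with DMSO within both AML001 sets, but edgeR called 0 genes in these comparisons. In the replicate 1 set MERTK was at 19.4 CPM with DMSO, 34.3 with palbociclib, 29.8 with quizartinib and 57.2 with the combination. In the replicate 2 set it was at 61.1, 102, 92.0 and 124 CPM. The last 2 are from the sparse libraries, where CPM without scaling is least certain. In AML903 it was at 7.78 to 14.2 CPM in DMSO, at 8.79 to 13.2 CPM with quizartinib and at 11.93 CPM with palbociclib.

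AML903 libraries differed along an axis that did not follow treatment. The mast cell and progenitor factor gene GATA2 was at 562 and 457 CPM in DMSO replicates 1 and 2 and at 112 and 150 CPM in DMSO replicates 3 and 4. With quizartinib it was at 354 and 349 CPM in replicates 1 and 2 and at 170 and 258 CPM in replicates 3 and 4, and the palbociclib library was at 96.3 CPM. MYCN was at 125 and 112 CPM in DMSO replicates 1 and 2 and at 17 and 22.3 CPM in the others, and HDC at 503 and 434 against 83.7 and 104 CPM. The granule gene LYZ was at 2409 CPM in DMSO replicate 1 and at 21460 to 46250 CPM in the other DMSO libraries.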
